A study of Mus musculus with 6 samples.

How the data were processed

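RNA sequencing libraries came from mouse bone marrow-derived macrophages, 3 controls given PBS and 3 given SA@BATMAN5 for 24 hours. Per the labels' protocols, marrow cells were grown with M-CSF at 10 ng/ml, polarised with IL-4 at 20 ng/ml for 24 hours, reseeded and then treated. The labels do not say whether IL-4 stayed in the medium during the treatment. Per the labels' protocols, 1.3 ug of total RNA went into each library, made with a SMARTer mRNA kit. The cells were wild type. Groups and replicate numbers were taken from the sample titles.

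One table of the whole series was used. It holds counts per gene in whole numbers, per the file headers and the values, and FPKM (fragments scaled by transcript length and library total) made by the authors, per the file headers. The deposited table also holds p-values and log2 fold changes of the authors' DESeq2 comparison, in which genes without a test carry a dash. The submitters' processing notes name HISAT2 2.2.0, StringTie 2.1.2, DESeq2 1.26.0 and the genome build GRCm39. The tool that counted reads per gene, the annotation and the strand setting are not given in the sources used here. Without a stated strand, reads of overlapping and antisense genes cannot be told apart, and reads shared by close paralogs may be divided in ways that depend on that tool. Identifiers of loci assembled by StringTie made up 674 of the tested rows and took 0.790% of control and 0.935% of treated counts. They stayed in library totals and tests and were not named. Column names carry N or S-5 in place of the group. S-5 was read as SA@BATMAN5, since it holds its initial and number, and N as the other group, which is a reading of the names and not a label. The reference in hand is built on GRCm38, another build than the authors', and the table has no coordinates, so none are given. All per-sample columns of counts and FPKM were used, while the authors' edgeR comparisons of single libraries were not used here.

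The table has 23034 genes, of which 5812 had no count in any library. Genes were kept with filterByExpr (minimum count 10, minimum total 15), leaving 13474. Counts were scaled by TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided, group as the single term) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 6.91%. CPM values use TMM-scaled totals. Standard errors of log2 fold changes came from the fitted weights and the quasi-likelihood variance. Where the control group had 0 counts, folds are bounds against 3 counts over the group, and with 1 to 3 counts a ratio with its exact 95% interval is given. Floors and intervals cover counting error only, since reads are not independent molecules.

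Before the data were examined, 29 gene lists, the alternatives and the rule for named genes were fixed. Lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, two-sided, adjusted over the 26 lists. The estimated correlation and fry were alternatives. The rule named the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold, at a mean of at least 5 CPM and with groups that did not overlap, leaving out predicted genes. It also named up to 2 members of each list with the smallest p, and Fcgr1, Fcgr2b, Fcgr3, Fcgr4, Nrp1, Arg1, Mrc1, Chil3, Retnla, Nos2, Tnf, Il1b, Il6 and Il10, which made 78 genes, not all of which are reported here. Other members named as going against their list, or as markers of another cell type, were chosen after their values were seen. Alternatives were DESeq2 size factors, library totals only, upper quartile, no filter, a filter at 1 CPM, the DESeq2 1.42.0 Wald test, limma-voom, a 2-fold threshold, the replicate number as a block, and each library left out in turn. Thinning to the shallowest library, limma on log2(FPKM + 1) with a pseudocount of 1, scaling factors without the 100 most abundant genes, and the comparison of the authors' p-values with DESeq2 run here were chosen after seeing the data. That comparison left out genes with extremely small p-values in either source, and took values within 0.1% as equal. Figures were drawn with matplotlib 3.10.9.

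Replicates were compared before they were averaged. Counts of pairs within a group differed by more than sampling noise (chi-square per degree of freedom 4.60 to 8.16), so each library was counted on its own. Separate preparations of 1 RNA sample would differ by more than that too, so this does not show that the replicates were separate cultures. The procedure was tested on simulated data drawn from the means and depths of this comparison (13317 genes tested), with 200 genes changed by 4-fold or less. In the real comparison 58.2% of tested genes were called, so recovery and scaling under such wide change were not tested. Of the changed genes that passed the filter, those changed 4-fold were recovered in 48 of 48 cases (100%) and 2-fold in 37 of 47 (78.7%). Genes changed 1.5-fold were recovered in 32 of 49 cases (65.3%) and 1.25-fold in 19 of 50 (38%). Changed genes that the filter removed are not in these shares. Of 13123 unchanged genes 11 were called, which was 7.48% of all calls and above the 5% aimed at, 94.3% of intervals covered the true value, the changed list had an adjusted p of 8.12e-13 and 0 of 20 unchanged lists were called.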

Results

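Gene expression was measured by RNA sequencing in mouse bone marrow-derived macrophages that had been polarised with interleukin-4 (M2 macrophages) and then exposed for 24 hours to PBS (control) or to SA@BATMAN5. The title of the series places the work with clusters of tuftsin, a short peptide derived from the immunoglobulin heavy chain, that are directed at Fc gamma receptors, and with macrophages in infections that follow sepsis. There were 3 libraries per group. Control libraries held 46022131, 38740103 and 47018154 counts. SA@BATMAN5 libraries held 36958470, 29739263 and 37212125 counts, so the groups did not overlap in depth (two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries can give). A floor of 3 counts corresponded to 0.0620 to 0.103 CPM (counts per 1000000 library counts, with library totals scaled by TMM) per library. The labels do not say whether replicates came from separate animals or cultures. The p-values of single genes therefore measure only the spread between these libraries, which may be technical. Camera p-values at the preset correlation of 0.01 compare a list's genes with other genes, taken as nearly independent. A very small camera p-value is thus not a measure of agreement between libraries. Levels below are mean CPM ± SD over n = 3 libraries per group, and log2 fold changes, SA@BATMAN5 over control, are given ± SE.

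The comparison asked which transcripts in the M2 macrophage cultures differed after SA@BATMAN5. Genes of the IL-4 programme fell, with Arg1 (arginase 1) going from 923 ± 13.4 to 8.81 ± 1.06 CPM and Mrc1 (the mannose receptor) from 1206 ± 75.1 to 66.9 ± 3.48 CPM. Inflammatory genes rose, among them Il1b from 0.970 ± 0.356 to 314 ± 11.6 CPM and Tnf from 12.4 ± 0.365 to 321 ± 20.5 CPM. Interferon-induced genes rose with them, as for Ifit3, from 1.52 ± 0.248 to 544 ± 29.2 CPM. Among Fc gamma receptors, Fcgr1 rose from 24.9 ± 2.28 to 129 ± 16.7 CPM and Fcgr3 fell from 631 ± 13.2 to 359 ± 9.38 CPM. Of 13474 genes tested with edgeR's quasi-likelihood test, 3980 were higher and 3866 lower with SA@BATMAN5 at a Benjamini-Hochberg adjusted p under 0.05. With upper-quartile scaling the split was 3239 higher and 4791 lower. A change of at least 2-fold was found for 1236 of the higher and 991 of the lower genes, and of at least 8-fold for 330 and 114. The other 5619 calls were under 2-fold.

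The genes with the largest rises among those the naming rule allowed began from very low control levels. That rule asked for a mean of at least 5 CPM and groups that did not overlap, and left out predicted genes. Gbp10, an interferon-inducible guanylate-binding protein gene, had 0 counts in the control libraries and 10.8 ± 1.28 CPM with SA@BATMAN5, which was at least 491-fold higher against a floor of 3 counts over the control group. Il12b, a subunit of interleukin-12, had 2 control counts and reached 38.3 ± 2.02 CPM, a ratio of 2601 with a 95% counting interval of 719 to 21482. Fpr2 and Fpr1, receptors for formylated bacterial peptides, reached 362 ± 18.3 and 177 ± 10.3 CPM from 0.125 ± 0.0399 and 0.130 ± 0.0857 CPM. Complement factor B (Cfb) went from 0.917 ± 0.231 to 1167 ± 17.7 CPM. The log2 fold changes of Cxcl3, Ifit1bl1 and Ms4a4c were 10.01 ± 0.50, 9.65 ± 0.63 and 9.22 ± 0.36. Among the largest falls, the organic anion transporter gene Slco2b1 went from 34.5 ± 4.06 CPM to 2 counts in the treated group, a ratio of 0.000576 with a 95% counting interval of 6.97e-05 to 0.00208. Kcnd3 (-8.34 ± 0.78), Il31ra (-7.32 ± 0.50), Ocstamp (-6.46 ± 0.10), Cdh1 (-5.88 ± 0.12), Map2 (-5.82 ± 0.22) and Irf4 (-5.23 ± 0.10) followed on the log2 scale among genes the naming rule allowed. Adjusted p-values (edgeR) of the 8 highest and, Arg1 included, 8 lowest genes under that rule were 6.55e-11 or smaller. Reads of Gbp10, Ifit1bl1, Cxcl3, Ms4a4c and Chil3 may be divided among close paralogs, so their own levels are uncertain.

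**Figure D1:**
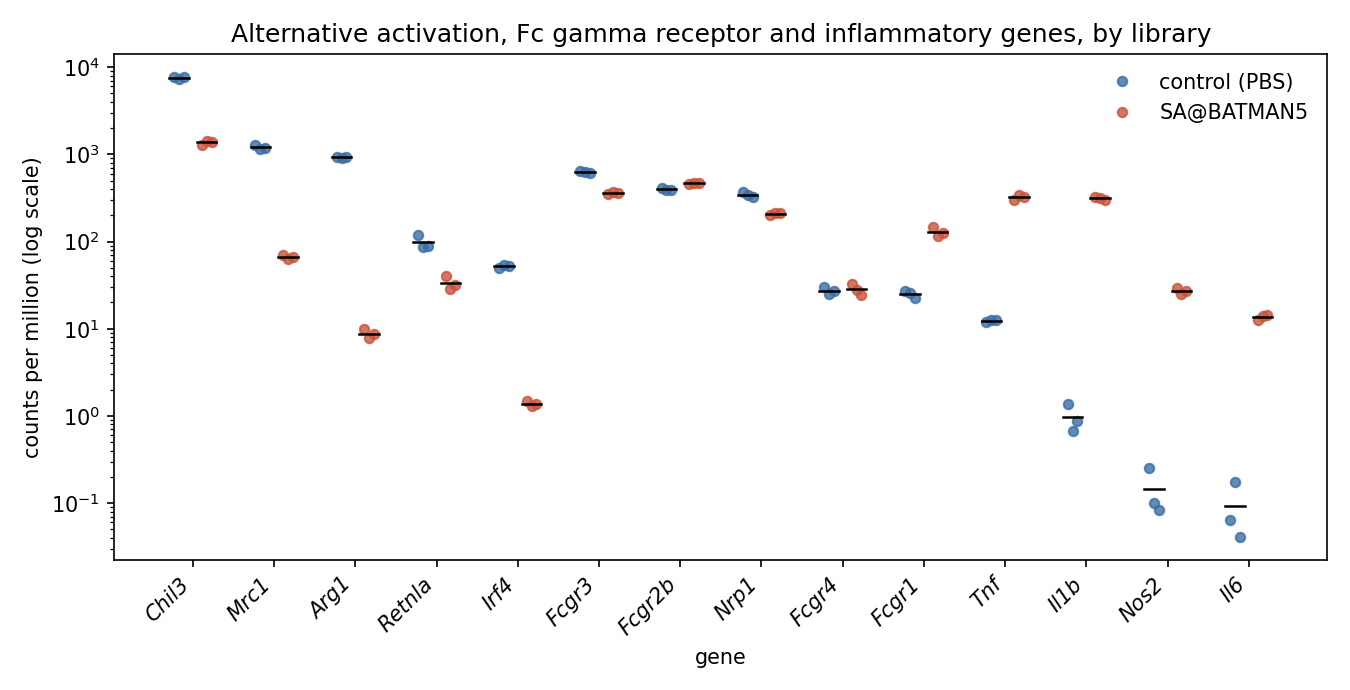
CPM (log scale) of 14 genes in each control (PBS, blue) and SA@BATMAN5 (red) library, 3 per group, with black bars at the group means. Arg1 fell from a mean of 923 to 8.81 CPM and Il1b rose from 0.970 to 314 CPM, while the libraries of both groups overlapped for Fcgr4 at 27.4 and 28.2 CPM.

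Of 23 measured genes in the IL-4 response list, 20 fell and 3 rose. Arg1 fell by 6.70 on the log2 scale (SE 0.06, adjusted p 6.01e-18, edgeR) and Mrc1 fell by 4.17 (SE 0.05, adjusted p 1.16e-16). Chil3, a chitinase-like lectin, went from 7533 ± 252 to 1375 ± 79.1 CPM. Retnla, which encodes the secreted protein Fizz1, went from 97.9 ± 18.7 to 33.6 ± 6.09 CPM. Irf4, a transcription factor of the IL-4 response, went from 51.8 ± 1.98 to 1.38 ± 0.0852 CPM. The members that rose were Slc7a2, Il4ra and Ccl22, of which Slc7a2 is a cationic amino acid transporter and Il4ra a chain of the IL-4 receptor. The list's median log2 fold change was -2.29, and it fell against other genes (camera, adjusted p 2.36e-25, and 0.00395 with an estimated correlation).

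Inflammatory genes moved the other way. In the pro-inflammatory list 21 of 23 measured genes rose and 1 fell, with a median log2 fold change of 6.18 (camera, adjusted p 1.02e-88, and 0.00174 with an estimated correlation). Clec4e, a receptor for mycobacterial glycolipid, rose from 6.69 ± 0.294 to 2731 ± 53.5 CPM, and Acod1, which makes itaconate, from 6.95 ± 0.409 to 2742 ± 33.5 CPM. Nos2, the inducible nitric oxide synthase, rose to 27.1 ± 1.96 CPM from 0.146 ± 0.0955 CPM, and Il6 to 13.7 ± 0.890 CPM from 0.0936 ± 0.0718 CPM. Il10 did not pass the test, at 0.252 ± 0.126 and 0.608 ± 0.398 CPM (adjusted p 0.0579, edgeR), and passed when SA@BATMAN5 replicate 2 was left out (adjusted p 0.0277). Of 22 NF-kappaB targets 18 rose and 2 fell (camera, adjusted p 4.67e-29). Sod2, the mitochondrial superoxide dismutase, rose from 59.1 ± 1.23 to 1185 ± 9.14 CPM, and Nfkbia, the inhibitor of NF-kappaB, from 19.8 ± 0.729 to 226 ± 4.44 CPM. Of 25 chemokine and chemokine receptor genes 14 rose and 9 fell (camera up, adjusted p 2.67e-07). Ccl5 rose from 5.43 ± 1.24 to 1629 ± 95.6 CPM and Cxcl16 from 80.1 ± 3.16 to 670 ± 10.6 CPM. The receptor genes Cx3cr1 and Ccrl2 rose as well. Those that fell included the ligands Ccl7, Cxcl14, Ccl6 and Ccl2 and the receptors Cxcr4, Ccr2 and Ccr1.

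All 29 measured genes of the type I interferon list rose, each by at least 2-fold, with a median log2 fold change of 4.86 (camera, adjusted p 5.68e-146). Ifit3 and Ifit2, antiviral RNA-binding proteins, rose by 8.49 ± 0.10 and 6.98 ± 0.06 on the log2 scale. In the antigen presentation list 14 of 22 genes rose and 6 fell, with camera up at an adjusted p of 4.73e-12, and the adjusted p was 0.0652 with an estimated correlation. Tapbp (tapasin) rose from 317 ± 3.94 to 1311 ± 13.5 CPM and Tap1, the peptide transporter subunit, from 39.6 ± 0.291 to 247 ± 8.84 CPM. The genes that fell were H2-DMa, H2-DMb1, Cd74, Ciita, Ifi30 and Lgmn, known from the class II and endosomal route, while the class II gene H2-Ab1 rose.

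The Fc gamma receptor genes went in different directions. Fcgr1, the high-affinity receptor, rose by 2.38 ± 0.08 on the log2 scale (adjusted p 1.04e-11, edgeR). Fcgr2b, the inhibitory receptor, rose from 398 ± 11.7 to 468 ± 8.01 CPM (log2 fold change 0.23 ± 0.03, adjusted p 2.26e-05). Fcgr3 fell by 0.81 on the log2 scale (SE 0.03, adjusted p 2.52e-11). Fcgr4 was at 27.4 ± 2.54 and 28.2 ± 4.14 CPM (log2 fold change 0.04 ± 0.10, adjusted p 0.720). Nrp1, described as a receptor for tuftsin, fell from 344 ± 22.0 to 209 ± 4.86 CPM. Reads of these related Fcgr genes may be divided in ways the counting tool decides. Of 19 genes for Fc gamma receptors and ITAM signalling 11 rose, 5 fell and 3 did not pass (camera up, adjusted p 0.0165), with an adjusted p of 0.202 with an estimated correlation. The Src family kinase gene Fgr rose from 23.7 ± 1.72 to 99.6 ± 1.69 CPM.

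The lists for uptake and breakdown of particles fell. Of 24 genes in the phagocytic and efferocytic receptor list 16 fell and 5 rose, with a median log2 fold change of -0.66 (camera down, adjusted p 0.00242). The camera adjusted p was 0.0554 with an estimated correlation. The list also holds genes that do not encode receptors, and of these C1qa, C1qb, C1qc, Gas6, Pros1, Mfge8, Elmo1 and Dock2 fell. Clec7a, the beta-glucan receptor dectin-1, fell from 3558 ± 106 to 1273 ± 39.0 CPM. Marco, a scavenger receptor for bacteria, rose from 0.262 ± 0.0670 to 91.0 ± 11.2 CPM, against the direction of the list. The receptor genes Axl, Msr1, Mertk and Itgb2 rose too, by 1.28, 1.23, 0.37 and 0.11 on the log2 scale. Of 33 lysosomal genes 23 fell and 5 rose (median log2 fold change -0.27, camera adjusted p 0.000218), with an adjusted p of 0.187 with an estimated correlation. Psap, the precursor of the saposins, fell from 18525 ± 152 to 9330 ± 156 CPM, and Atp6v0d2, a subunit of the vacuolar proton pump, from 1243 ± 40.4 to 273 ± 6.07 CPM. Of 20 autophagy genes 6 rose, 6 fell and 8 did not pass, and the list did not differ from other genes (camera, adjusted p 0.926). Its median was -0.01 and its mean 0.03, and with library totals only 4 rose and 8 fell. Sqstm1, the autophagy receptor p62, rose from 340 ± 10.2 to 1087 ± 33.1 CPM, and Tax1bp1 from 192 ± 7.97 to 270 ± 5.05 CPM. Sqstm1 also stands in the NRF2 and oxidative stress list.

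Oxidase and stress-defence genes rose. In the NADPH oxidase and antimicrobial list 17 of 18 genes rose and Ltf (lactoferrin) did not pass, with a median log2 fold change of 1.25 (camera, adjusted p 2.35e-22). Lcn2, which binds bacterial siderophores, rose from 0.632 ± 0.104 to 155 ± 13.4 CPM. Of 22 NRF2 and oxidative stress genes 20 rose and 2 fell, with a median of 1.42 (camera, adjusted p 1.32e-19). The cystine transporter gene Slc7a11 went from 74.3 ± 2.37 to 664 ± 54.2 CPM, and Fth1, ferritin heavy chain, from 10611 ± 177 to 29859 ± 990 CPM. The members that fell were Ftl1, ferritin light chain, and Osgin1. Of 20 immune checkpoint and regulator genes 12 rose and 7 fell, with a median of 0.99 (camera up, adjusted p 6.82e-05). The inhibitory receptor genes Pilra and Siglece rose, from 17.9 ± 1.46 to 284 ± 7.36 CPM and from 0.392 ± 0.0308 to 38.8 ± 1.87 CPM. Among the 7 that fell was Pdcd1lg2, also in the IL-4 response list, from 17.1 ± 0.287 to 0.955 ± 0.402 CPM.

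Metabolic lists did not pass the list test, though single genes did. Of 26 glycolysis and hypoxia genes 13 rose and 7 fell (camera, adjusted p 0.524), which became 11 and 10 with library totals only and 11 and 11 with upper-quartile scaling. Among them were Pfkl, liver phosphofructokinase, at 44.2 ± 1.24 and 101 ± 0.870 CPM and Vegfa at 129 ± 1.70 and 55.3 ± 2.55 CPM. Of 33 TCA cycle and respiratory chain genes 6 rose and 16 fell (adjusted p 0.315), against 3 and 20 with library totals only and 3 and 21 with the upper quartile, and Fh1 and Idh3a fell by 0.61 (SE 0.06) and 0.46 (SE 0.04) on the log2 scale. Of 24 cholesterol synthesis and uptake genes 5 rose and 11 fell (adjusted p 0.187). Dhcr7, a late enzyme of cholesterol synthesis, fell from 101 ± 3.14 to 36.6 ± 0.401 CPM and Cyp51 from 110 ± 4.74 to 69.5 ± 1.86 CPM. Of 23 LXR target and lipid handling genes 7 rose and 13 fell (adjusted p 0.407). Acsl1, a fatty acyl-CoA synthetase, rose from 35.5 ± 1.02 to 743 ± 15.5 CPM, and Fabp4, a fatty acid carrier, fell from 116 ± 1.05 to 20.5 ± 0.692 CPM. Of 24 unfolded protein and integrated stress response genes 9 rose and 8 fell (adjusted p 0.926). The median (0.02) and mean (0.13) of that list were above 0 and its camera direction was down, and with library totals only its median was -0.06, with 8 genes higher and 11 lower. Its Psat1, of serine synthesis, fell from 112 ± 2.29 to 53.3 ± 3.27 CPM.

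Cell cycle genes fell. Of 30 proliferation genes 27 fell and 1 rose, with a median log2 fold change of -0.88 (camera, adjusted p 8.12e-05), and the adjusted p was 0.285 with an estimated correlation. Pcna, the sliding clamp of DNA replication, went from 412 ± 3.72 to 190 ± 2.50 CPM and Ccnd1 (cyclin D1) from 140 ± 3.67 to 53.9 ± 2.14 CPM. The member that rose was Bub1b. Of 21 immediate early genes 14 fell and 3 rose (median -0.36, camera adjusted p 0.00329), with an adjusted p of 0.0590 with an estimated correlation. Myc fell from 51.0 ± 2.85 to 7.88 ± 0.701 CPM, and Klf6 rose from 175 ± 1.92 to 321 ± 4.33 CPM.

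Macrophage identity genes were split, with 13 of 20 higher and 6 lower (camera, adjusted p 0.0582). The galectin gene Lgals3 fell from 5864 ± 73.6 to 1994 ± 11.1 CPM and Cd33 rose from 24.0 ± 0.964 to 142 ± 4.72 CPM. That list passed without control replicate 1 (adjusted p 0.0476), without SA@BATMAN5 replicate 2 (0.0436) and without SA@BATMAN5 replicate 3 (0.0458). Of 27 actin, adhesion and matrix genes 15 fell and 10 rose (camera down, adjusted p 0.0406), with an adjusted p of 0.152 with an estimated correlation. Without SA@BATMAN5 replicate 1, 2 or 3 its adjusted p was 0.0658, 0.0892 or 0.0801. The gelatinase gene Mmp9 rose from 57.0 ± 0.310 to 1205 ± 56.7 CPM, and Plau, the urokinase gene, fell from 772 ± 6.52 to 128 ± 4.61 CPM. Of 11 osteoclast genes 7 fell and 4 rose, with a median of -0.29 (camera down, adjusted p 9.04e-05). Ocstamp, needed for fusion of osteoclast precursors, fell from 124 ± 1.35 to 1.39 ± 0.221 CPM.

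**Figure D2:**
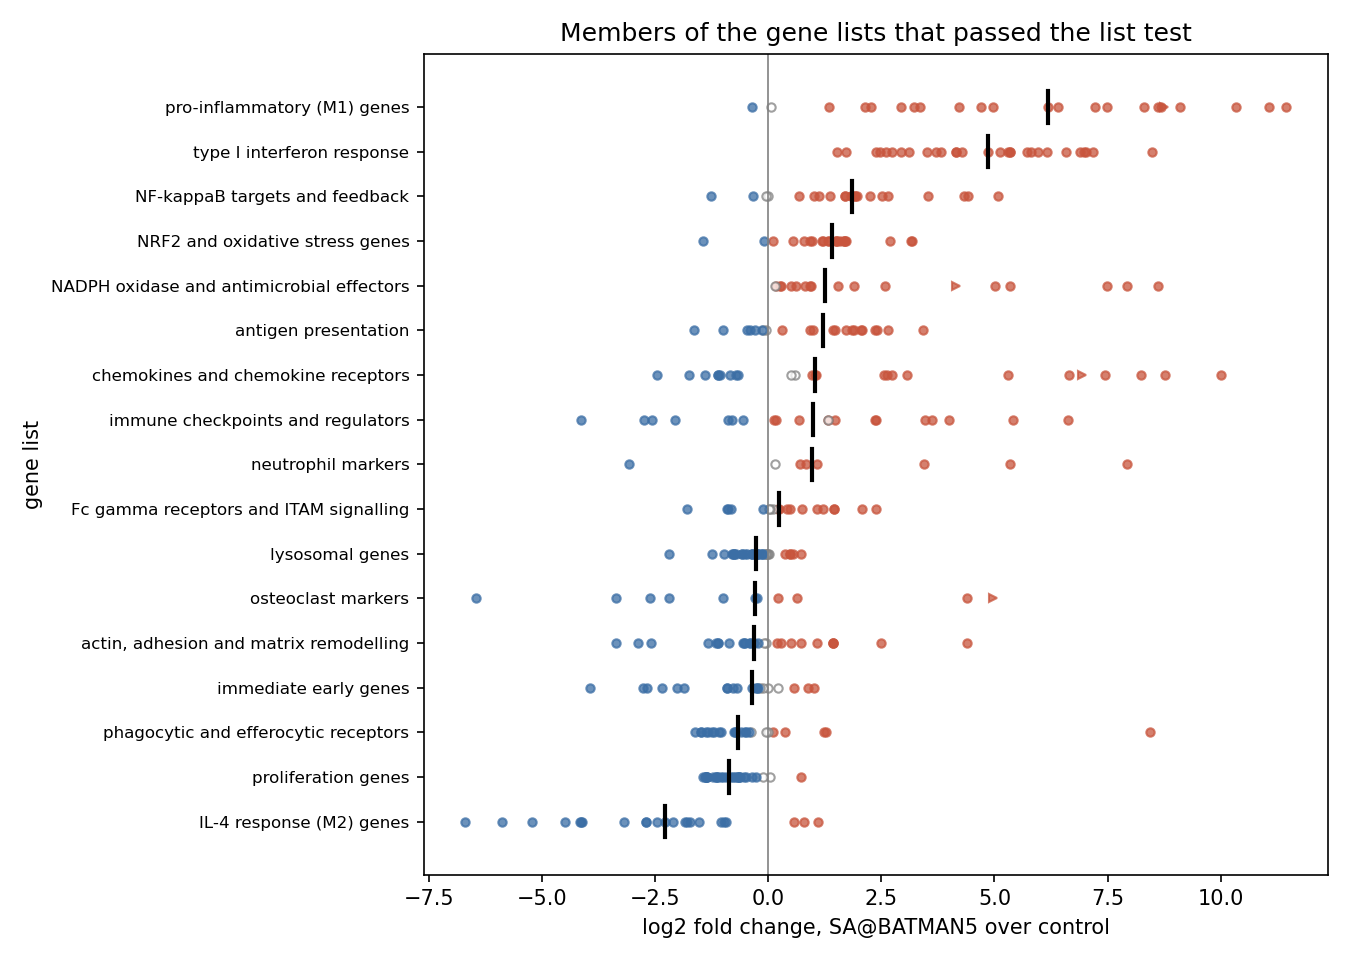
Log2 fold change (SA@BATMAN5 over control) of each measured member of the 17 gene lists that passed the camera test, with filled red and blue marks for members that rose and fell, open marks for members that did not pass, and black bars at list medians. Triangles mark members with 0 control counts, drawn at their bound against 3 counts over the group. Medians ran from -2.29 in the IL-4 response list to 6.18 in the pro-inflammatory list.

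Markers of other cell types were tested as lists too. Of 8 measured neutrophil genes 6 rose and 1 fell (camera up, adjusted p 0.000690), with an adjusted p of 0.0540 with an estimated correlation. S100a8 rose from 5.63 ± 0.104 to 61.7 ± 4.96 CPM, S100a9 went from 1.73 ± 0.238 to 3.10 ± 0.378 CPM, and Ly6g, Mpo, Retnlg and Ctsg had 0 counts in both groups, which allows up to 3 counts. Lcn2, Camp, Ltf and Mmp8 of this list also stand in another list. Of 9 dendritic cell genes 3 rose and 2 fell (camera, adjusted p 0.926), or 3 and 3 with library totals only. The median of that list was -0.17, its mean 0.25 and its camera direction up. Its Bst1 rose from 16.2 ± 2.26 to 170 ± 6.05 CPM and Cd83 fell from 43.8 ± 5.65 to 2.37 ± 0.142 CPM. Of 11 fibroblast and stromal genes 8 rose and 2 fell (camera, adjusted p 0.487). Pdgfrb rose from 8.04 ± 1.49 to 30.9 ± 3.20 CPM and Cxcl12 fell from 19.4 ± 2.17 to 5.64 ± 0.858 CPM. Col1a1 stood at 382 ± 38.5 and 514 ± 33.0 CPM. Transcripts of these stromal markers were thus present in both groups. Whether the cultures held stromal cells was not tested, so not every transcript need come from macrophages. Too few members were measured for a list test of lymphocyte, mast cell and erythroid markers. Among 4 lymphocyte genes Klrb1c rose from 0.813 ± 0.230 to 3.27 ± 0.841 CPM. Cd79a was at 0.145 ± 0.0974 and 0.394 ± 0.124 CPM (adjusted p 0.0498), and this call was lost without control replicate 2 or 3 (adjusted p 0.156 and 0.162) and without SA@BATMAN5 replicate 1, 2 or 3 (0.0516, 0.0924 and 0.197). Of 2 mast cell and basophil genes Hdc rose from 0.0715 ± 0.0755 to 0.564 ± 0.168 CPM. The 1 measured gene of the erythroid and megakaryocyte list, Itga2b, was at 1.10 ± 0.319 and 1.02 ± 0.320 CPM (adjusted p 0.851).

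Across the 29 lists, 26 had enough members for the list test and 17 passed, 10 up and 7 down. With an estimated correlation 9 passed, which were the IL-4 response, pro-inflammatory, oxidase and antimicrobial, type I interferon, NF-kappaB, chemokine, checkpoint, NRF2 and osteoclast lists. Their camera adjusted p-values then ran from 0.00174 (pro-inflammatory) to 0.0487 (osteoclast). Counts of members adjusted over the list alone were equal to those over all genes in 22 lists. Adjusted over the list alone, 7 antigen presentation genes fell, 13 checkpoint genes rose, 7 TCA cycle genes rose, 9 unfolded protein response genes fell, 7 macrophage identity genes fell, 3 dendritic cell genes fell and 1 lymphocyte gene rose.

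The groups were well apart as whole profiles. The first principal component of log2 CPM held 84.9% of the variance, and correlations across genes, which are not independent replicates, were 0.988 to 0.991 within groups and 0.913 to 0.916 between them. Mitochondrially encoded genes took 3.89% ± 0.0646 of control counts and 2.85% ± 0.102 of treated counts, and ribosomal protein genes 2.87% ± 0.0618 and 2.09% ± 0.0264 (SD, n = 3, two-sided exact permutation p = 0.1 each, the smallest possible). The 10 most abundant genes of each library took 14.2% ± 0.0378 and 13.1% ± 0.0546 of counts, the 100 most abundant 32.8% ± 0.124 and 30.9% ± 0.0671, and haemoglobin genes had 0 counts in every library.

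The authors' deposited table of their DESeq2 comparison gives values for 12043 genes, of which 998 were higher and 830 lower at a p under 0.05 and at least 2-fold. The column header does not say whether that p is adjusted. DESeq2 run here on the same 12043 genes gave unadjusted p-values within 0.1% of it for all 11612 genes compared, and adjusted ones for 13, so it was read as unadjusted. Adjusted here over those genes, 998 higher and 826 lower remained. All 1828 genes at an unadjusted p under 0.05 and at least 2-fold had the same sign here and 1826 were also called here at 2-fold or more. The other 2, Arhgap33 and Gpc2, named after their values were seen, had adjusted p-values of 0.0574 and 0.0794 by edgeR here. Their deposited DESeq2 p-values, read as unadjusted, were 0.0205 and 0.0275, and 0.0348 and 0.0455 once adjusted over the authors' genes. Of 2227 genes called here at 2-fold or more, 394 had no value in the authors' deposited table.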

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

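Thinning to the shallowest library, limma on log2(FPKM + 1) and scaling factors without the 100 most abundant genes were chosen after seeing the data. Requiring at least 2-fold left 1236 higher and 991 lower genes, by construction of the threshold, and an estimated correlation left 9 of 17 gene lists. Over the 500 most variable genes the first principal component held 91.7% of the variance. Every other count of higher or lower genes stayed within 1.5 times the reported 3980 and 3866. Leaving out each library in turn gave 3677 to 3777 higher and 3627 to 3707 lower genes. Library totals only gave 3291 higher and 4694 lower, the upper quartile 3239 and 4791, and FPKM 3100 and 4500, with median log2 shifts of -0.074, -0.081 and -0.070. No gene called both as reported and in another setting turned direction. Deviations of same-numbered libraries correlated at 0.038, -0.007 and 0.035, while 4 of 6 libraries correlated best with their own number. With 3 libraries per group these values do not settle whether replicate numbers pair the libraries. With replicate number as a block 3927 genes were higher and 3818 lower and 17 lists passed, with the actin, adhesion and matrix list lost (adjusted p 0.0961) and macrophage identity gained (0.0481). Among 78 named genes, 76 kept their side of the threshold in all settings that tested them, and Cd79a and Il10 did not. Fcgr4 and Itga2b, not called in any of these settings, turned direction in some, as for Fcgr4 from 0.04 to -0.03 with library totals only and Itga2b to 0.10 without control replicate 1. Cd79a, at 20 and 40 counts, had adjusted p-values of 0.0504 to 0.197 where it lost its call, and the cause was not tested. With fry 25 of 26 lists passed, a test that does not compare a list with other genes. Depth limits genes under about 0.1 CPM, near the floor of 3 counts. Pseudocount, filter and quantile alternatives planned for FPKM alone were not run, as counts were at hand.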

Other observations

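The symbol families, the thinning, the test of abundant genes, the splits, the comparison of S100a9 with S100a8 and the reading of the interferon list for a carried ligand were tests chosen after the results were seen. Genes were grouped by the letters that open their symbols, and 207 such families with at least 8 tested members were tested with camera. At the preset correlation 10 passed, 8 up and 2 down, and with an estimated correlation 0 passed (7 at an unadjusted p under 0.05), although the Ifi, Gbp and Parp families had the smallest unadjusted p-values there (0.00268, 0.00433 and 0.00496). All 10 Gbp genes rose, with Gbp2 going from 22.6 to 1374 CPM and Gbp5 from 1.59 to 188 CPM. Of 15 Ifi genes 13 rose and Ifi30, a lysosomal thiol reductase, fell. Of 12 Parp genes 7 rose and 1 fell, led by Parp14 from 65.5 to 734 CPM, while Parp1 was at 94.2 and 88.0 CPM (adjusted p 0.0605, edgeR), and with library totals only 2 Ifi and 3 Parp genes fell. All 10 Psmb genes rose, with the immunoproteasome subunits Psmb8 (log2 fold change 2.06), Psmb9 (1.90) and Psmb10 (1.23) ahead of the other members, the highest of which was Psmb7 (0.62). Of 47 Rpl genes 42 fell, with a median log2 fold change of -0.38 and -0.46 with library totals only, while Rpl24 rose (0.72). The Rps family, which as grouped also holds kinase genes such as Rps6ka1, had 35 of 43 members lower. Among 10 Tlr genes 6 rose and 4 fell, with Tlr2 at 7.19 and 224 CPM and Tlr4 at 64.7 and 58.0 CPM. Of the rest, 8 of 10 Cxcl and 25 of 45 Trim genes rose, while 8 of 19 Clec genes rose and 8 fell, with a median of -0.16 against a camera direction of up. Pseudogenes and close copies make single Rpl, Rps, Gbp and Ifi levels uncertain.

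Ferritin chains moved apart. Fth1 rose from 10611 to 29859 CPM and Ftl1 went from 16765 to 15788 CPM. Among osteoclast genes Ckb, Itgb3 and Atp6v0d2 fell, while Acp5 rose from 294 to 453 CPM and Calcr, with 0 control counts, was at least 31.2-fold higher against 3 counts over the group.

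The share of tested genes called was 58.2%. Unequal depth predicts far fewer than the 7846 calls once libraries are thinned to the shallowest, but 7666 genes were then called, 7509 of them also called as reported. A few abundant genes taking counts predicts 1 common shift of all others. That shift was 0.0419 on the log2 scale with library totals only, from shares of 32.1% and 30.1% for the 100 most abundant. Of 13374 other genes 8214 differed from it, and 5228 of these lay on the other side of 0. With library totals only the median shift against the reported values was -0.074, so both counts may include genes that moved with the bulk. At 2-fold or more, 1131 called genes lay on the side of the common shift and 1086 on the other, which 1 common shift does not give. A shift caused by genes outside the 100 most abundant was not tested. The treatment, by which the groups differ in the labels, remains open as the explanation. On chance the splits say nothing, since the 6 libraries allow only 10, too few for a share under 0.05, and each other split mixes both groups, which widens the spread: the real split, the 1 with as many calls, gave 7846 and the highest other 0 by edgeR (69 to 128 genes at an unadjusted p under 0.05, and at most 4 calls by DESeq2).

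Of 8 neutrophil markers 6 rose and 1 fell, and the list passed at the preset correlation (adjusted p 0.000690) but not with an estimated one (0.0540). Neutrophils in the treated cultures would bring S100a9 with S100a8, but the rise of S100a9 was 2.44% ± 0.477 (SE) of the rise of S100a8 in CPM, against a bound of 50% set here without a neutrophil profile in hand, Cxcr2 fell from 1.40 to 0.179 CPM, and Ly6g, Mpo and Retnlg had 0 counts. These values argue against neutrophils as the source of the whole S100a8 rise. Expression of S100a8, Lcn2 and Camp by the macrophages may account for it, which was not tested.

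Interferon and inflammatory genes rose together, and the median log2 fold change of the interferon list was 4.86. This may follow from SA@BATMAN5 itself or from a toll-like receptor ligand carried with the preparation. These cannot be told apart, because treated cultures received the whole preparation and control cultures PBS. No culture here received a part of the preparation alone, and the labels do not name its parts.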
